A study of Homo sapiens with 30 samples.

How the data were processed

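RNA from MCF-7 cells, an established human breast adenocarcinoma line that carries the estrogen receptor, was measured on Affymetrix HG-U133A_2 oligonucleotide arrays. Per the labels, the cells were transfected with 20 nM of a control siRNA (siCtrl), an siRNA against ERK1 (siERK1) or an siRNA against ERK2 (siERK2) for 60 h. They were then given 0.1% ethanol (vehicle) or 10 nM estradiol (E2) for 4 h or 24 h. The 30 arrays fall into 12 groups by siRNA, agent and time, with 3 arrays per group at 4 h and 2 per group at 24 h. The labels number the arrays of a group but do not say whether these came from separate cultures or from the same RNA. The spread between arrays, on which every p-value rests, may therefore be technical.

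The deposited table held a value per probe set and array, read as log2 intensity from its range, with a lowest value of 2.14 shared by all arrays. How the authors summarized and normalized the arrays is not given in the sources used here. Array medians lay between 4.27 and 4.50, and upper quartiles between 8.31 and 8.55. These gaps of 0.23 and 0.24 were above the limit of 0.1 set for using the values unchanged, so quantile normalization over the 30 arrays (limma) was the main setting. For arrays, their number limits the precision. A value at the shared floor is an upper bound on the signal, so a fold change against a group at the floor is limited by it.

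Of 22277 probe sets, 62 controls were left out, and 19064 of the rest named exactly 1 gene in the annotation table. Another 1043 named several genes and 2108 none. For each of the 11963 genes, the probe set with the highest mean over the 30 arrays stood for the gene; 7653 genes had only 1. Values of 3620 genes stayed below 3 on every array, and 768 genes did not vary. They remained among the genes tested. MAPK3, the gene of ERK1, had 1 probe set. MAPK1, the gene of ERK2, was named by 0 probe sets, so the level of the siERK2 target was not analysed here. Of 240 other probe sets of named genes, 2 moved against the chosen one and passed the test. Both belong to TGFB2 and are given with that gene.

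A linear model with the 12 group means was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean level). The groups of 2 arrays thereby shared an estimate of the spread with the groups of 3, with 18 residual degrees of freedom. The 19 comparisons were E2 against vehicle for each siRNA and time, each siRNA pair in vehicle at each time, the differences of the E2 effect between siRNAs at each time, and the difference between times in siCtrl. Tests covered both directions. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, and "rose", "fell", "higher" and "lower" below refer to genes that passed. Errors of log2 fold changes are the model's standard errors (SE), and errors of group means are SD.

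Genes named in the text follow a rule set, like the lists, tests and settings unless said otherwise, before the data were examined. Per comparison it takes up to 10 genes with the largest change each way whose groups do not overlap array by array, or up to 8 each way for a difference of E2 effects without that condition. It adds MAPK3 and, for a gene list described, up to 4 members with the smallest adjusted p. Chance separates 3 arrays from 3 in 10% of genes, and 2 from 2 more often.

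The 19 gene lists were estrogen-induced genes, estrogen-repressed genes, DNA replication and S phase, G2 and mitosis, ERK pathway output genes, immediate early genes, MAPK cascade components, interferon response, p53 targets, cholesterol and fatty acid synthesis, amino acid and ER stress response, cAMP and CREB targets, ribosome biogenesis and MYC targets, heat shock and chaperones, hypoxia and glycolysis, and marker genes of luminal epithelial, basal and mesenchymal, fibroblast and leukocyte cells. They were written from general knowledge, and some share members, at most 3 between a pair. Each list was tested against all other genes with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 361 tests. The same test with a correlation estimated from the arrays was an alternative. Members are counted adjusted over all genes and adjusted over the list alone. An E2 response score compared the whole response between siRNAs at each time. It took the genes whose E2 effect averaged over the siRNAs passed, turned the sign of repressed genes, compared medians, and was tested with limma fry on the difference of E2 effects.

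The procedure was tested on simulated data with the measured spread of each gene at each time. All groups of a time shared that spread, and the noise of genes was independent. Single-gene changes were put only into genes with a mean clear of the array floor. The larger spread of single groups and the correlation of genes are not covered. At 4 h, changes of 1 log2 unit were recovered for 49.3% of genes in E2 against vehicle, 61.2% in siERK2 against siCtrl and 31.3% in a difference of E2 effects. Changes of 2 units were recovered for 92.4%, 98.5% and 71.2%. A list shifted by 0.5 passed while 0 of 18 others did. With no change put in, each comparison at 4 h called at most 3 genes in any of 10 draws. At 24 h the pooled model then called medians of 342.5 to 373.5 genes. It assumes a common spread, but 24 h arrays spread more than those at 4 h. The 24 h arrays fitted alone, without a pair of arrays described in the report, called at most 1. The draws had the equal spread this fit assumes, so they cannot test it. Counts at 24 h are given beside both.

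Alternatives tried were the values as deposited, array medians subtracted, the dimmest 40% of genes left out, all probe sets, no variance trend, each time fitted alone, array weights, the array number as a covariate, the siRNA effect averaged over vehicle and E2, a minimum change of 1.5-fold, other gene choices for the score, and each array left out in turn. Chosen after the data were seen were leaving out the 2 arrays with a high 3' to 5' signal, fitting the 24 h arrays alone without them, and the run of array numbers at 24 h as a block.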

Results

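Gene expression was measured in MCF-7 breast cancer cells on 30 arrays. Per the labels, the cells carried a control siRNA (siCtrl), an siRNA against ERK1 or an siRNA against ERK2, and received vehicle or estradiol (E2), the main natural estrogen. ERK1 and ERK2 are the kinases at the end of the MAPK cascade. At 4 h there were 18 arrays with 3 in each group, and at 24 h there were 12 with 2 in each group. The comparisons ask which genes E2 changed, which genes each siRNA changed without hormone, and whether the E2 effect differed between the siRNAs. Values are log2 intensities of 11963 genes after quantile normalization, and changes are log2 fold changes between group means unless a fold is given. Of 361 tests of gene lists, 97 passed with the preset correlation and 46 also with an estimated one. For a list given with its test, the adjusted p with an estimated correlation follows where the call was lost; not every lost call is described.

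RNA quality differed between the times. Control probe sets at the 3' and 5' ends of GAPDH and ACTB gauge how complete the copied RNA was, and a high 3' excess goes with shortened RNA. The GAPDH difference was 0.069 to 0.24 on the 18 arrays at 4 h and 0.54 to 1.23 on 10 arrays at 24 h. It was 5.54 on siCtrl vehicle replicate 2 and 5.73 on siERK2 vehicle replicate 2 at 24 h, called the 2 high 3' arrays below. The ACTB difference was 7.03 and 9.49 on this pair, 2.37 to 6.57 on the other 24 h arrays and 0.62 to 1.05 at 4 h. Across probe sets, which are not independent, the lowest correlation of an array with its group was 0.996 to 0.998 at 4 h and 0.958 to 0.994 at 24 h. The number of genes in each comparison at 24 h is therefore given also without the 2 high 3' arrays and with the 24 h arrays fitted alone without them, called the 24 h arrays alone below. Either way the siCtrl and siERK2 vehicle groups at 24 h keep 1 array each, whose spread is assumed to equal that of the other groups. With no change simulated, the model of all 30 arrays called a median of 342.5 to 373.5 genes in the 24 h comparisons. The simulation gave every group of 24 h the same spread.

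**Figure D1:**
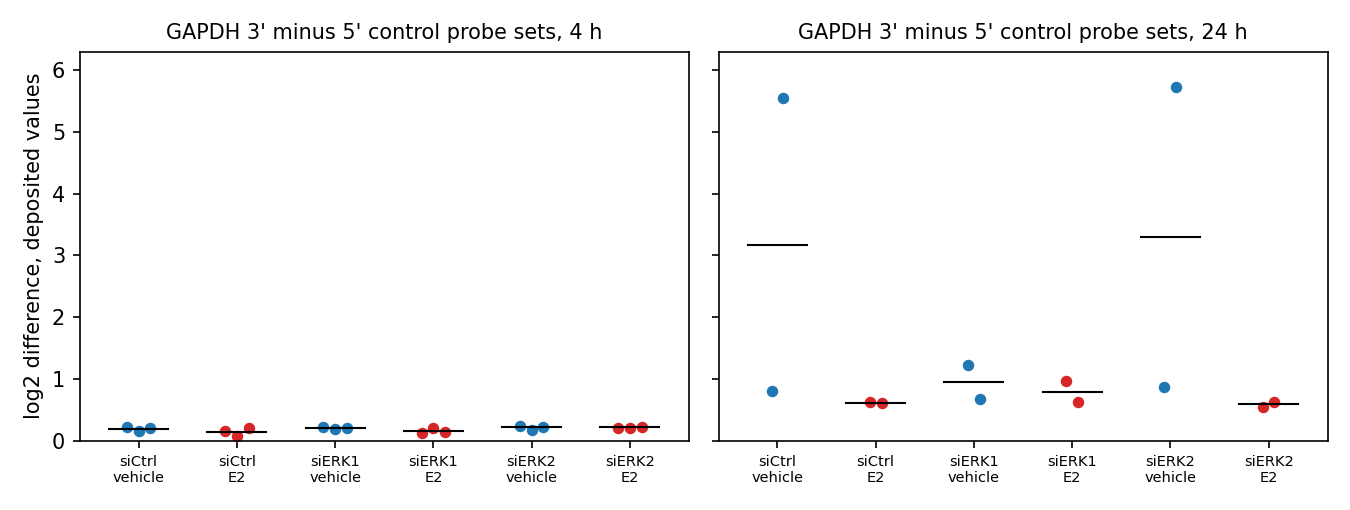
The log2 difference between the 3' and 5' GAPDH control probe sets (vertical axis, deposited values) is plotted for each array (points, blue for vehicle and red for E2) by siRNA and agent at 4 h and 24 h, with a line at each group mean. siCtrl vehicle replicate 2 at 5.54 and siERK2 vehicle replicate 2 at 5.73 lie above all other arrays, which reach 1.23 at most.

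The siRNA against ERK1 lowered the RNA of its target. MAPK3 (212046_x_at), the gene of ERK1, was 3.17-fold lower in siERK1 than in siCtrl cells in vehicle at 4 h (log2 fold change -1.67, SE 0.28, adjusted p = 0.00119), at 6.56 ± 0.13 against 8.22 ± 0.085 (SD, n = 3). In E2 at 4 h it was 3.81-fold lower (log2 fold change -1.93, adjusted p = 0.000231), and in vehicle at 24 h 3.92-fold lower (log2 fold change -1.97, SE 0.35, adjusted p = 0.00144). In E2 at 24 h the log2 fold change was -1.24 and did not pass (adjusted p = 0.12). The 24 h vehicle call was lost when the 24 h arrays were fitted alone without the 2 high 3' arrays (log2 fold change -1.87, adjusted p = 0.481). In siERK2 cells the log2 fold changes of MAPK3 were -0.19 and 0.10 at 4 h and -0.0048 and -0.12 at 24 h, in vehicle and E2, with an adjusted p of 1 each. The level of MAPK1, the gene of ERK2, was not analysed because 0 probe sets named it.

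**Figure D2:**
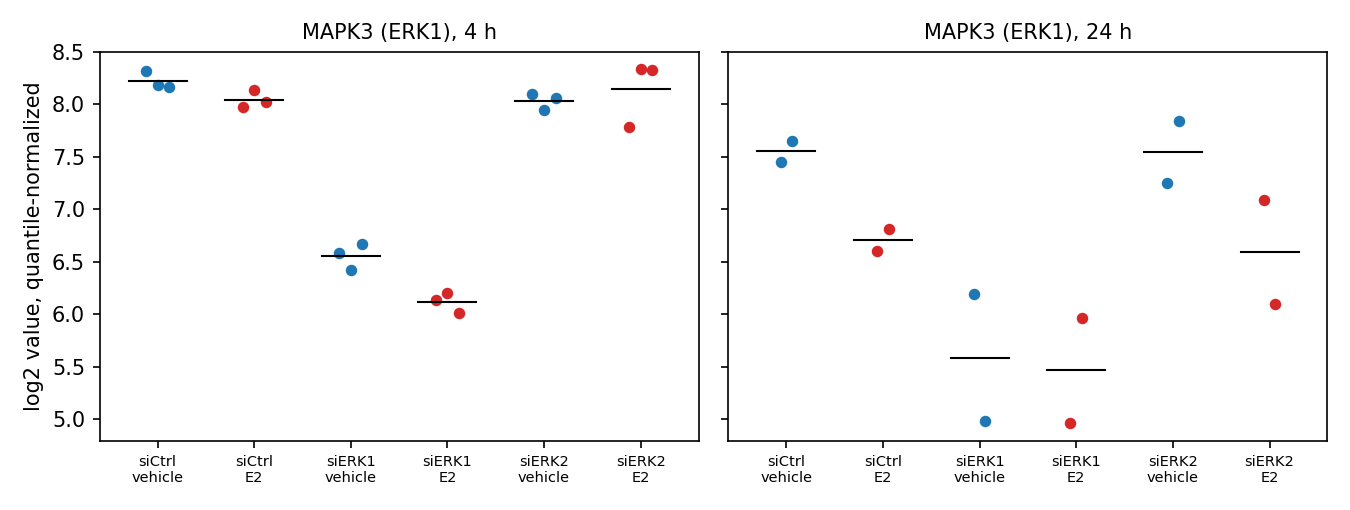
The log2 value of MAPK3 after quantile normalization (vertical axis, starting above the array floor) is plotted for each array (points, blue for vehicle and red for E2) by siRNA and agent at 4 h and 24 h, with a line at each group mean. In vehicle at 4 h the mean is 6.56 in siERK1 and 8.22 in siCtrl cells.

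E2 for 4 h in siCtrl cells gives the early hormone response with the control siRNA. SERPINB9, which encodes an inhibitor of granzyme B, rose from 2.24, near the array floor, to 8.34 (log2 fold change 6.10, SE 0.19, adjusted p = 6.4e-14). KCNK5, a potassium channel gene, rose 38.9-fold. GREB1 (205862_at), a cofactor of the estrogen receptor, rose 38.3-fold from 3.92 ± 0.27 to 9.18 ± 0.31 (SD, n = 3; log2 fold change 5.26, SE 0.23, adjusted p = 6.75e-12). FST, which encodes the activin-binding protein follistatin, and FOS, a subunit of the transcription factor AP-1, rose 36.5-fold and 30.3-fold. TNFRSF11B, the gene of the decoy receptor osteoprotegerin, was 28.0-fold lower (log2 fold change -4.81, SE 0.34, adjusted p = 7.54e-09), and ARID5B, a chromatin regulator, 12.3-fold lower.

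Of the genes tested for E2 at 4 h in siCtrl cells, 549 passed, 344 higher and 205 lower, and 475 of them changed at least 1.5-fold. Among 34 measured estrogen-induced genes, 27 rose, 0 fell and 7 did not pass (29 rose adjusted over the list alone), with a median of 2.01 and HSPB8, a small heat shock protein gene, up by 1.91 (camera adjusted p = 1.36e-82). Of 24 estrogen-repressed genes, 9 fell, 2 rose and 13 did not pass (12 and 2 adjusted over the list alone, median -0.37, adjusted p = 5.55e-08). EFNA1, an ephrin ligand gene, fell by 2.07 and CCNG2, an unconventional cyclin tied to growth arrest, fell by 2.62, while KLF4, a transcription factor gene, rose by 1.09. In the list of ribosome biogenesis and MYC targets, 6 of 17 rose, 0 fell and 11 did not pass (7 rose adjusted over the list alone, median 0.45, adjusted p = 3.3e-07), among them WDR12 by 0.63 and NOP16 by 0.89, both of ribosome assembly. The hypoxia and glycolysis list of 17 had 4 that rose, 1 that fell and 12 that did not pass (5 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.0152, adjusted p = 0.117 with an estimated correlation). PFKFB3, a regulator of glycolysis, rose by 2.75 and the oxygen sensor gene EGLN3 changed by -2.42. The count was 835 without the 2 high 3' arrays of 24 h, which share the spread estimate.

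In siERK1 cells E2 for 4 h raised and lowered many of the genes it changed in siCtrl cells. SERPINB9 rose by 6.56 (SE 0.19, adjusted p = 1.68e-14), MN1, a transcriptional coactivator gene, by 5.83 (SE 0.08, adjusted p = 1.58e-20) from 2.25, near the floor, and KCNK5 by 5.32. TGFB2, which encodes a transforming growth factor, was 32.4-fold lower by probe set 209909_s_at (log2 fold change -5.02, SE 0.28, adjusted p = 1.72e-10), to a level near the floor, and TNFRSF11B was 24.5-fold lower. In all, 552 genes passed, 314 higher and 238 lower, 474 of them by at least 1.5-fold. Of the 344 genes higher in siCtrl cells, 234 were higher here (9.03 by chance), and of the 205 lower genes, 142 were lower (4.08 by chance). Estrogen-induced genes rose in 24 of 34 cases, 0 fell and 10 did not pass (28 rose adjusted over the list alone, median 1.66, adjusted p = 5.72e-62), with STC2, a secreted glycoprotein gene, up by 3.56. Estrogen-repressed genes fell in 9 cases and rose in 4 of 24, with 11 not past (14 and 5 adjusted over the list alone, median -0.67, adjusted p = 2.06e-07). EFNA1 changed by -2.97 and ID3, an inhibitor of differentiation, by -3.32. Ribosome biogenesis genes rose in 3 of 17 cases, 0 fell and 14 did not pass (4 rose adjusted over the list alone, median 0.35, adjusted p = 0.000319), RRS1 by 0.78.

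E2 for 4 h in siERK2 cells changed 833 genes, 439 higher and 394 lower, 711 of them by at least 1.5-fold. FST rose by 7.21 (SE 0.19, adjusted p = 1.29e-15), SERPINB9 by 6.94 (SE 0.19, adjusted p = 2.99e-15) and P2RY2, a nucleotide receptor gene, by 6.43. TGFB2 fell by 5.13 and DKK1, which encodes a Wnt inhibitor, fell by 4.51 (SE 0.46, adjusted p = 8.21e-07). Of the genes higher in siCtrl cells, 280 were higher here (12.6 by chance), and 175 of the lower ones were lower (6.75 by chance). Estrogen-induced genes rose in 26 of 34 cases, with 0 fallen and 8 not past (28 rose adjusted over the list alone, median 1.74, adjusted p = 1.29e-51). Of 24 estrogen-repressed genes, 10 fell, 3 rose and 11 did not pass (13 and 4 adjusted over the list alone, median -0.70, adjusted p = 1.06e-06). Ribosome biogenesis genes rose in 6 of 17 cases, 0 fell and 11 did not pass (6 rose adjusted over the list alone, median 0.47, adjusted p = 7.84e-06), NOP16 by 1.24. None of the 33 G2 and mitosis genes passed (0 adjusted over the list alone), though the list's median was -0.25 (adjusted p = 0.00328, adjusted p = 0.391 with an estimated correlation). The count of genes was 1253 without the 2 high 3' arrays.

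Without hormone at 4 h, 560 genes differed between siERK1 and siCtrl cells, 251 higher and 309 lower in siERK1, 409 of them by at least 1.5-fold. ADAM2, a gene of the ADAM family of membrane proteins, was 7.34-fold higher in siERK1 than in siCtrl cells (log2 fold change 2.88, SE 0.30, adjusted p = 7.34e-06), and MSMB, which encodes a secreted microseminoprotein, 6.10-fold higher. L1CAM, a neural cell adhesion gene, was 6.65-fold lower (log2 fold change -2.73, SE 0.40, adjusted p = 0.000331), and TNF, the gene of tumor necrosis factor, 5.96-fold lower. Among 17 immediate early genes, which growth factor signals switch on within minutes, 3 fell, 0 rose and 14 did not pass (7 fell adjusted over the list alone, median -0.32, adjusted p = 9.49e-05). IER3 changed by -1.05, the mRNA decay factor gene ZFP36 by -0.70 and FOS by -0.73. Of 24 estrogen-repressed genes, 4 fell, 0 rose and 20 did not pass (6 fell and 1 rose adjusted over the list alone, median -0.19, adjusted p = 0.000273), among them NEDD9, a scaffold protein gene, at -1.55. Estrogen-induced genes went both ways, with 4 of 34 higher, 5 lower and 25 not past (5 and 7 adjusted over the list alone, median 0.049, adjusted p = 0.876). TFF3, a trefoil factor gene of secretory epithelium, rose by 2.06, TFF1 (205009_at), a trefoil factor gene and textbook estrogen target, by 1.99 from 12.04 to 14.03, and the receptor kinase gene RET by 1.95.

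Other lists moved with siERK1 in vehicle at 4 h without holding an estimated correlation. Of 33 G2 and mitosis genes, 2 were higher and 31 did not pass (12 higher adjusted over the list alone, median 0.43, adjusted p = 7.2e-08, adjusted p = 0.103 with an estimated correlation). CCNB1, a mitotic cyclin, changed by 0.54. DNA replication genes were higher in 4 of 33 cases with 29 not past (8 adjusted over the list alone, median 0.29, adjusted p = 8.28e-05, adjusted p = 0.175 with an estimated correlation). Of 18 ERK pathway output genes, 2 fell and 16 did not pass (4 fell adjusted over the list alone, median -0.058, adjusted p = 0.0217, adjusted p = 0.0779 with an estimated correlation). MAPK cascade components had 1 of 16 higher, MAP2K1, the gene of the kinase MEK1 upstream of ERK, at 0.38 (1 adjusted over the list alone, median 0.27, adjusted p = 0.0198, adjusted p = 0.0604 with an estimated correlation). The p53 target list of 14 had 2 that fell and 1 that rose (the same counts adjusted over the list alone, median -0.15, adjusted p = 0.0295, adjusted p = 0.1 with an estimated correlation). The death receptor gene TNFRSF10B changed by -1.16. With array medians subtracted, the share of genes higher moved from 44.8% to 55.9%. The number of genes was 337, 316 and 307 without siCtrl vehicle replicate 1, siCtrl vehicle replicate 2 or siERK1 vehicle replicate 3, and 1207 without the 2 high 3' arrays.

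Without hormone at 4 h, the siRNA against ERK2 lowered cell cycle genes together and raised several estrogen-induced genes. CYP2C8, which encodes a cytochrome P450 enzyme, was 15.0-fold higher in siERK2 than in siCtrl cells (log2 fold change 3.91, SE 0.21, adjusted p = 1.06e-09), TSPAN8, a tetraspanin gene, 13.8-fold higher and TFF3 10.1-fold higher. HCAR3, a hydroxycarboxylic acid receptor gene, was 7.36-fold lower (log2 fold change -2.88, SE 0.36, adjusted p = 2.46e-05). Of 33 G2 and mitosis genes, 29 fell, 0 rose and 4 did not pass (31 fell adjusted over the list alone, median -1.19, adjusted p = 2.3e-42). The mitotic cyclin CCNB2 changed by -1.24 (SE 0.12), the mitotic activator CDC20 by -1.17 and the proliferation marker MKI67 by -2.05. Of 33 genes of DNA replication and S phase, 19 fell, 0 rose and 14 did not pass (26 fell adjusted over the list alone, median -0.66, adjusted p = 1.48e-26). The primase gene PRIM1 changed by -1.35 and the thymidine kinase gene TK1 by -1.12.

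Estrogen-induced genes in siERK2 cells in vehicle at 4 h rose in 13 of 34 cases and fell in 1, with 20 not past (16 and 5 adjusted over the list alone, median 0.30, adjusted p = 1.54e-06). TFF1 rose by 2.85 (adjusted p = 1.95e-08), from 12.04 ± 0.13 to 14.89 ± 0.041 (SD, n = 3), and GREB1 by 2.90. The TFF1 level in siERK2 cells is above the 99th percentile of every array, at most 14.40, and near the array ceiling, so its rise is limited if the signal saturates. Of 16 genes of cholesterol and fatty acid synthesis, 5 rose, 0 fell and 11 did not pass (7 rose adjusted over the list alone, median 0.57, adjusted p = 2.58e-05). The sterol oxidase gene MSMO1 changed by 0.97 and INSIG1, a regulator of sterol synthesis, by 1.21. Among immediate early genes 2 of 17 fell, EGR1 at -1.51 and EGR3 at -1.16, both transcription factor genes, 0 rose and 15 did not pass (9 fell adjusted over the list alone, median -0.59, adjusted p = 1.54e-05). ERK pathway output genes fell in 1 of 18 cases (2 adjusted over the list alone, median -0.020, adjusted p = 0.0367, adjusted p = 0.102 with an estimated correlation). In all, 839 genes passed, 391 higher and 448 lower, 617 of them by at least 1.5-fold. The number was 546, 525 and 511 without siCtrl vehicle replicate 1, siCtrl vehicle replicate 2 or siERK2 vehicle replicate 3, and 1559 without the 2 high 3' arrays.

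The direct comparison of siERK2 with siERK1 in vehicle at 4 h asks whether the siRNAs against the kinases differ in effect. LTB, the gene of lymphotoxin beta, was 9.39-fold higher in siERK2 cells (log2 fold change 3.23, SE 0.30, adjusted p = 4.4e-07) and CYP2C8 8.27-fold higher. NCAM2, a cell adhesion gene, was 8.09-fold lower (log2 fold change -3.02, SE 0.26, adjusted p = 1.79e-07), and NCAPH, a condensin subunit gene, 7.88-fold lower. Of 33 G2 and mitosis genes, 31 were lower, 0 higher and 2 did not pass (32 lower adjusted over the list alone, median -1.64, adjusted p = 2.6e-43). CCNB2 changed by -1.63. DNA replication genes were lower in 24 of 33 cases, with 0 higher and 9 not past (30 lower adjusted over the list alone, median -0.93, adjusted p = 1.64e-27). GINS2, a replication helicase subunit, changed by -1.29. Estrogen-induced genes were higher in 13 of 34 cases and lower in 1, with 20 not past (13 and 3 adjusted over the list alone, median 0.21, adjusted p = 6.37e-06). The carbonic anhydrase gene CA12 changed by 1.85. In all, 1331 genes passed, 651 higher and 680 lower, 1000 of them by at least 1.5-fold, and 2287 passed without the 2 high 3' arrays.

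**Figure D3:**
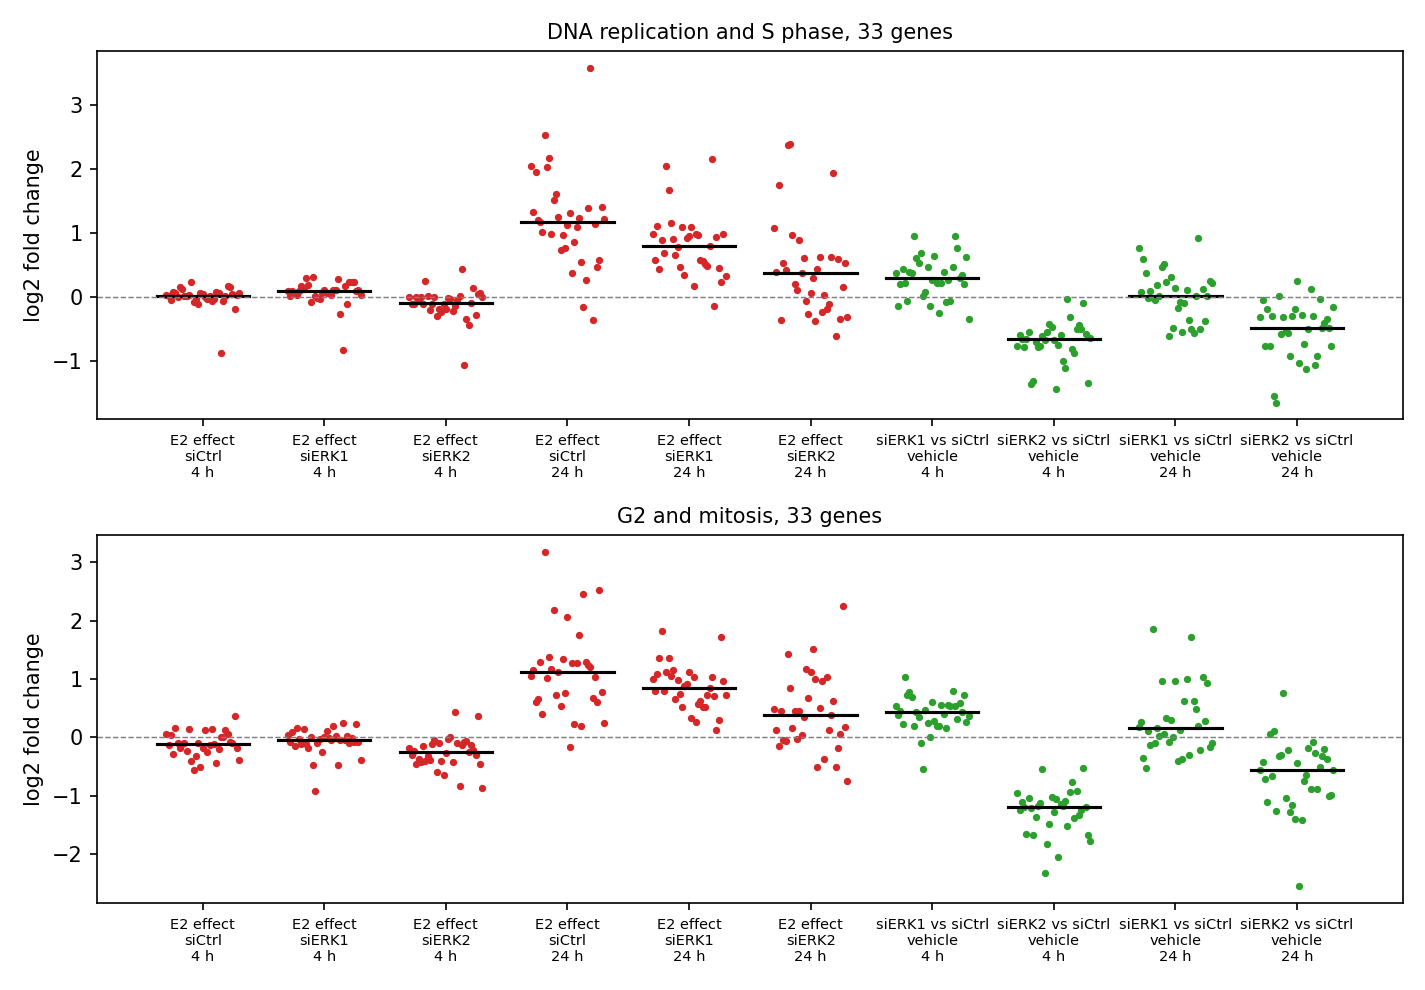
Log2 fold changes (vertical axis) of the 33 measured genes of DNA replication and S phase and the 33 of G2 and mitosis (points) are plotted for E2 effects (red) and for each siRNA against siCtrl in vehicle (green), with a line at each median. For siERK2 in vehicle at 4 h the medians are -0.66 and -1.19, and for E2 in siCtrl cells at 24 h they are 1.16 and 1.13; the 24 h vehicle groups of siCtrl and siERK2 each hold 1 of the 2 high 3' arrays.

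The E2 effect at 4 h differed between siERK1 and siCtrl cells for 26 genes (13 higher, 13 lower), 24 by at least 1.5-fold. MTUS2, a microtubule-associated gene, differed by 2.73 (SE 0.40, adjusted p = 0.00268). FILIP1L, a regulator of cell movement, differed by 2.22 (SE 0.23, adjusted p = 3.24e-05). E2 lowered FILIP1L from 5.38 to 2.79 in siCtrl cells, but siERK1 vehicle was already close to the floor at 3.05. CEACAM1, a cell adhesion gene, differed by -2.25 (SE 0.21, adjusted p = 1.41e-05) and ADM, the gene of the peptide hormone adrenomedullin, by -2.16. TGFB2 differed by -2.00 by probe set 209909_s_at (adjusted p = 0.0343), where E2 brought siERK1 cells near the floor, and by 1.66 by 209908_s_at (adjusted p = 6.62e-05). Of 34 estrogen-induced genes, 2 had a lower effect, RET at -1.62 and TFF1 at -1.36, 0 a higher one and 32 did not pass (7 lower adjusted over the list alone, median -0.15, adjusted p = 1.31e-08). Both had started higher in siERK1 cells: RET went from 7.09 to 10.16 in siCtrl and from 9.04 to 10.50 in siERK1 cells, and TFF1 from 12.04 to 13.91 and from 14.03 to 14.55, near the array ceiling. The number was 17 without siCtrl vehicle replicate 2 and 7 with the dimmest genes left out.

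Between siERK2 and siCtrl cells the E2 effect at 4 h differed for 44 genes, 30 with a higher and 14 with a lower effect, 42 of them by at least 1.5-fold. SSTR2, a somatostatin receptor gene at the floor in both vehicle groups, reached 5.65 with E2 in siERK2 and 2.43 in siCtrl cells (difference 3.22, SE 0.27, adjusted p = 9.25e-07), and HSD11B2, the cortisol-inactivating enzyme, also at the floor in vehicle, differed by 2.35. GREB1 differed by -2.54 (SE 0.33, adjusted p = 0.000323): it rose from 3.92 to 9.18 in siCtrl and from 6.82 to 9.54 in siERK2 cells. TFF1 differed by -1.73 (SE 0.27, adjusted p = 0.00248), at 12.04 and 13.91 in siCtrl and 14.89 and 15.03 in siERK2 cells. Both siERK2 levels are near the array ceiling, so saturation was not excluded for this difference. TGFB2 differed by -2.12 by 209909_s_at (adjusted p = 0.0139) and moved the other way by 209908_s_at (adjusted p = 0.000187). Of 34 estrogen-induced genes, 4 had a lower effect, 1 a higher one and 29 did not pass (7 and 3 adjusted over the list alone, median -0.082, adjusted p = 0.000502). None of 17 immediate early genes passed (1 higher adjusted over the list alone), with a list median of 0.26 (adjusted p = 0.000856). The number was 29 without siCtrl vehicle replicate 2, 13 with the dimmest genes left out and 76 without the 2 high 3' arrays.

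Between siERK2 and siERK1 cells the E2 effect at 4 h differed for 31 genes, 21 with a higher and 10 with a lower effect in siERK2, 27 of them by at least 1.5-fold. FST had a higher effect by 3.09 (SE 0.27, adjusted p = 6.29e-06), LRRC15, a membrane protein gene, by 2.77 and PGR, the progesterone receptor gene, by 2.28 (SE 0.35, adjusted p = 0.00305). BMP4, a bone morphogenetic protein gene, had a lower effect, at -2.04 (SE 0.26, adjusted p = 0.000309). None of the DNA replication or the G2 and mitosis genes passed (0 each adjusted over the list alone), with list medians of -0.17 and -0.22 (adjusted p = 0.000172 and 0.0009, and adjusted p = 0.202 and 0.327 with an estimated correlation). The number was 13 with the dimmest genes left out and 56 without the 2 high 3' arrays.

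The E2 response score took 1403 genes at 4 h, 700 induced and 703 repressed. Its median was 0.59 in siCtrl and 0.77 in siERK2 cells, a difference of 0.18 (fry adjusted p = 0.000599), and 0.60 in siERK1 cells, a difference of 0.0087 (adjusted p = 0.831). With genes chosen by their call in siCtrl cells alone, a choice that favours siCtrl, the differences were 0.0032 for siERK2 (adjusted p = 0.442) and -0.23 for siERK1 (adjusted p = 0.00204).

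**Figure D4:**
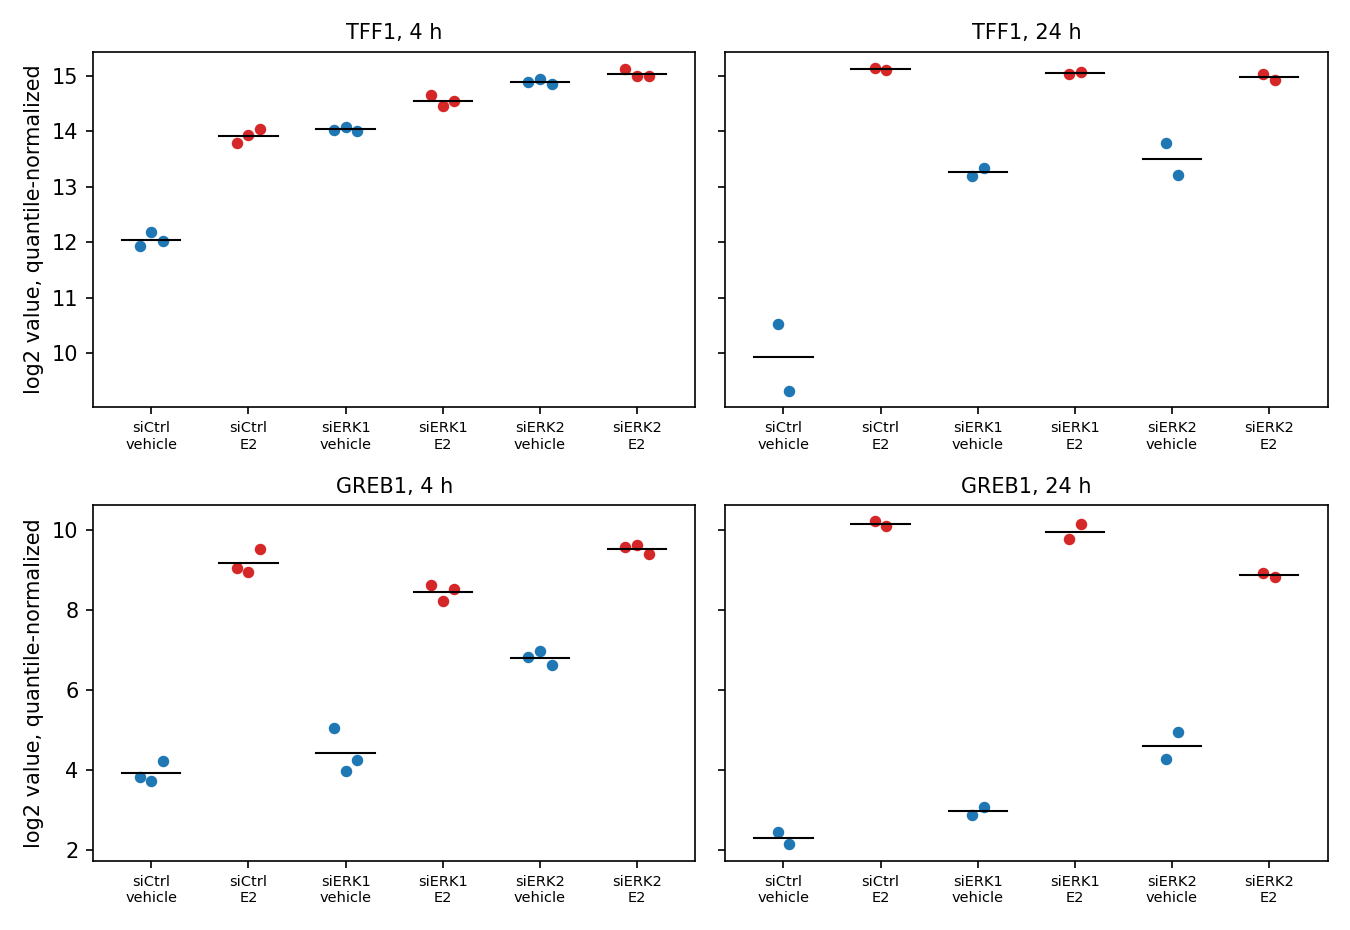
Log2 values of TFF1 and GREB1 after quantile normalization (vertical axes, starting above 0) are plotted for each array (points, blue for vehicle and red for E2) by siRNA and agent at 4 h and 24 h, with a line at each group mean. In vehicle at 4 h TFF1 is at 12.04 in siCtrl and 14.89 in siERK2 cells, and GREB1 at 3.92 and 6.82.

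E2 for 24 h in siCtrl cells raised estrogen targets and cell cycle genes. GREB1 rose from 2.29 ± 0.21, near the floor, to 10.17 ± 0.078 (SD, n = 2; log2 fold change 7.88, SE 0.29, adjusted p = 4.53e-13). CXCL12 and CCL2, chemokine genes, rose 100.1-fold and 98.4-fold, and PTGS2, the gene of cyclooxygenase-2, 59.7-fold. VTCN1, an immune checkpoint ligand gene, was 88.7-fold lower (log2 fold change -6.47, SE 0.23, adjusted p = 3.86e-13), and TM4SF1, a membrane protein gene, 71.1-fold lower. TFF1 rose by 5.20 (SE 0.23, adjusted p = 7.24e-12), to 15.12, near the array ceiling. In all, 3195 genes passed, 1431 higher and 1764 lower, 2533 of them by at least 1.5-fold. With no change simulated, a median of 342.5 genes passed here.

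Beside the gene groups for E2 at 24 h in siCtrl cells stands the GAPDH 3' excess of 5.54 on vehicle replicate 2. Among 34 estrogen-induced genes, 26 rose, 1 fell and 7 did not pass (29 and 1 adjusted over the list alone, median 2.01, adjusted p = 1.79e-27), and of 24 estrogen-repressed genes, 13 fell, 3 rose and 8 did not pass (15 and 4 adjusted over the list alone, median -1.01, adjusted p = 0.000287). IL1R1, an interleukin receptor gene, changed by -4.72. Of 33 DNA replication genes, 28 rose, 0 fell and 5 did not pass (28 rose adjusted over the list alone, median 1.16, adjusted p = 9.5e-18). GINS2 changed by 1.51 (adjusted p = 1.09e-08) and FEN1, a flap endonuclease gene, by 1.13. G2 and mitosis genes rose in 23 of 33 cases, 0 fell and 10 did not pass (24 rose adjusted over the list alone, median 1.13, adjusted p = 5.68e-12). CCNB2 changed by 1.15 and the mitotic kinase AURKB by 3.18. Ribosome biogenesis genes rose in 12 of 17 cases, 0 fell and 5 did not pass (12 rose adjusted over the list alone, median 0.92, adjusted p = 4.22e-07). Luminal epithelial markers fell in 7 of 13 cases, 0 rose and 6 did not pass (8 fell adjusted over the list alone, median -0.53, adjusted p = 0.00784, adjusted p = 0.15 with an estimated correlation). The mucin MUC1 changed by -1.47 and the estrogen receptor gene ESR1 by -1.07. Heat shock and chaperone genes rose in 7 of 13 cases, 1 fell and 5 did not pass (8 and 1 adjusted over the list alone, median 0.86, adjusted p = 0.0198, adjusted p = 0.0957 with an estimated correlation). Of 19 genes of the amino acid and ER stress response, 8 rose, 2 fell and 9 did not pass (8 and 2 adjusted over the list alone, median 0.87, adjusted p = 0.0152, adjusted p = 0.392 with an estimated correlation, adjusted p = 0.202 without the 2 high 3' arrays). With the 24 h arrays fitted alone without that array and its siERK2 counterpart, 953 genes passed. There 23 estrogen-induced, 16 DNA replication, 8 G2 and mitosis, 3 ribosome biogenesis, 3 estrogen-repressed, 3 amino acid and ER stress and 0 heat shock genes rose. In the same fit 11 estrogen-repressed genes, 3 luminal markers, 1 heat shock gene and 1 amino acid and ER stress gene fell. In all 3 fits 755 genes passed, while all 12 arrays of 24 h fitted alone gave 629 and array weights 265. The count was 2590 without the 2 high 3' arrays, 1791 without vehicle replicate 2 and 1746 without E2 replicate 2, and with array medians subtracted the share of genes higher moved from 44.8% to 57.9%.

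In siERK1 cells E2 for 24 h raised PTGS2 by 9.30 (SE 0.24, adjusted p = 1.07e-15) and MMP13, a collagenase gene, by 7.68 (SE 0.09, adjusted p = 5.42e-22), both from the floor, and GREB1 by 6.99. LMO3, a transcription cofactor gene, was 46.3-fold lower (log2 fold change -5.53, SE 0.45, adjusted p = 3.1e-08) and GNE, the key enzyme gene of sialic acid synthesis, 41.2-fold lower. In all, 2041 genes passed, 1025 higher and 1016 lower, 1661 of them by at least 1.5-fold, against 349 with no change simulated. Of the genes higher in siCtrl cells at 24 h, 565 were higher here (123 by chance), and 611 of the lower ones were lower (149.8 by chance). Neither high 3' array is in this comparison, but both set part of its spread: 3397 genes passed without them, 1089 with the 24 h arrays fitted alone, and 926 in all 3 fits. All 12 arrays of 24 h fitted alone gave 487, and array weights 1665. Estrogen-induced genes rose in 24 of 34 cases, 0 fell and 10 did not pass (26 rose and 2 fell adjusted over the list alone, median 1.70, adjusted p = 9.82e-26). IL17RB, an interleukin receptor gene, changed by 4.43. Estrogen-repressed genes fell in 10 of 24 cases, 2 rose and 12 did not pass (11 and 2 adjusted over the list alone, median -0.61, adjusted p = 0.000768). DNA replication genes rose in 18 of 33 cases, 0 fell and 15 did not pass (22 rose adjusted over the list alone, median 0.79, adjusted p = 5.45e-13). FEN1 changed by 0.93. G2 and mitosis genes also rose in 18 of 33 cases, with 0 fallen and 15 not past (21 rose adjusted over the list alone, median 0.84, adjusted p = 2.76e-10, adjusted p = 0.0561 with an estimated correlation). CDC20 changed by 1.15. Ribosome biogenesis genes rose in 11 of 17 cases, 0 fell and 6 did not pass (13 rose adjusted over the list alone, median 0.95, adjusted p = 2.2e-09). WDR12 changed by 1.54. Interferon response genes fell in 8 of 27 cases and rose in 1, with 18 not past (9 and 1 adjusted over the list alone, median -0.53, adjusted p = 0.00957, adjusted p = 0.358 with an estimated correlation). The interferon-induced gene IFI44L changed by -2.15. In the fit of the 24 h arrays alone, 21 estrogen-induced, 15 DNA replication, 14 G2 and mitosis, 7 ribosome biogenesis and 3 estrogen-repressed genes rose, and 10 estrogen-repressed and 7 interferon response genes fell. The count of genes was 1336 without vehicle replicate 1 and 1308 without E2 replicate 1.

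In siERK2 cells E2 for 24 h raised PTGS2 by 8.43 (SE 0.24, adjusted p = 6.67e-15), from 2.17, near the floor, UGT2B15, a steroid glucuronidation enzyme gene, by 6.78 (SE 0.25, adjusted p = 2.75e-13) and COL21A1, a collagen gene, by 6.70. LMO3 was 38.3-fold lower (log2 fold change -5.26, SE 0.45, adjusted p = 5.29e-08) and FBN2, a fibrillin gene, 36.4-fold lower. In all, 2931 genes passed, 1089 higher and 1842 lower, 2322 of them by at least 1.5-fold, against 371.5 with no change simulated. Of the genes higher in siCtrl cells, 571 were higher here (130.3 by chance), and 839 of the lower ones were lower (271.6 by chance). Array medians subtracted moved the median of all genes to -0.12, the share of genes higher from 37.2% to 20.4% and the number of genes to 5232. With the 24 h arrays fitted alone without the 2 high 3' arrays, 989 genes passed. Without those arrays in the model of both times 2840 passed, and 725 in all 3 fits. All 12 arrays of 24 h fitted alone gave 586, and array weights 224. The count was 1631 without E2 replicate 2.

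The gene groups of this E2 effect in siERK2 cells at 24 h stand beside a GAPDH 3' excess of 5.73 on vehicle replicate 2. Estrogen-induced genes rose in 21 of 34 cases and fell in 1, with 12 not past (22 and 1 adjusted over the list alone, median 1.49, adjusted p = 6.57e-17). Of 17 immediate early genes, 7 rose, 1 fell and 9 did not pass (9 and 1 adjusted over the list alone, median 0.64, adjusted p = 3.88e-05). EGR3 changed by 3.98 and MYC, a growth-promoting transcription factor, by 3.83 (adjusted p = 6.58e-07). Ribosome biogenesis genes rose in 10 of 17 cases, 0 fell and 7 did not pass (10 rose adjusted over the list alone, median 1.01, adjusted p = 6.27e-08). Heat shock and chaperone genes rose in 5 of 13 cases, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone, median 0.65, adjusted p = 0.00162). The mitochondrial chaperonin HSPD1 changed by 0.65 (adjusted p = 0.106 with the 24 h arrays alone). DNA replication genes rose in 11 of 33 cases, 0 fell and 22 did not pass (12 rose adjusted over the list alone, median 0.37, adjusted p = 0.00195, adjusted p = 0.297 with an estimated correlation). CDC6, a replication licensing gene, changed by 2.38. G2 and mitosis genes rose in 8 of 33 cases, 0 fell and 25 did not pass (9 rose adjusted over the list alone, median 0.39, adjusted p = 0.00784, adjusted p = 0.431 with an estimated correlation, adjusted p = 0.0836 without the 2 high 3' arrays). Genes of the cAMP and CREB target list rose in 4 of 13 cases and fell in 1, with 8 not past (4 and 1 adjusted over the list alone, median 0.070, adjusted p = 0.0262, adjusted p = 0.132 with an estimated correlation). The glycoprotein hormone subunit CGA changed by 4.72. When the 24 h arrays were fitted alone without the 2 high 3' arrays, 17 estrogen-induced, 4 immediate early, 2 ribosome biogenesis, 2 DNA replication, 4 cAMP and CREB, 0 heat shock and 0 G2 and mitosis genes rose, and 1 cAMP and CREB gene fell.

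Without hormone at 24 h, siERK1 cells were compared with a siCtrl vehicle group that holds a high 3' array, with a GAPDH excess of 5.54. ZMYM6, a zinc finger gene, was 10.9-fold higher (log2 fold change 3.44, SE 1.01, adjusted p = 0.0365), a call lost without the 2 high 3' arrays (adjusted p = 0.144), and TRAPPC6A, a vesicle transport gene, 10.7-fold higher, lost with the 24 h arrays fitted alone (adjusted p = 0.572). TFF1 was 10.1-fold higher (log2 fold change 3.34, SE 0.23, adjusted p = 5.58e-08), at 13.27 ± 0.11 against 9.92 ± 0.85 (SD, n = 2), and passed in both (adjusted p = 1.86e-12 and 0.000324), where 1 siCtrl vehicle array, at 10.52, is left. GAS1, a growth arrest gene, was 15.6-fold lower (log2 fold change -3.97, SE 0.29, adjusted p = 8.28e-08), and L1CAM 15.4-fold lower, both also past with the 24 h arrays alone (adjusted p = 0.00191 and 0.0372), against that 1 array. In all, 1218 genes passed, 629 higher and 589 lower, 1012 of them by at least 1.5-fold, against 355.5 with no change simulated, 1038 without the 2 high 3' arrays and 193 with the 24 h arrays fitted alone without them. All 12 arrays of 24 h fitted alone gave 16 genes and array weights 14. Only 60 genes passed in the 3 fits together, and 7 of the 20 taken by the naming rule passed with the 24 h arrays alone. Of 18 ERK pathway output genes, 2 fell, the phosphatase gene DUSP6 at -1.75 (adjusted p = 0.186 with the 24 h arrays alone) and PHLDA1 at -0.86, and 16 did not pass (3 fell adjusted over the list alone, median -0.19, adjusted p = 0.0431, adjusted p = 0.112 with an estimated correlation). Basal and mesenchymal markers fell in 1 of 10 cases, the matrix protein gene SPARC at -0.87 (6 fell adjusted over the list alone, median -0.45, adjusted p = 0.0231, adjusted p = 0.143 with an estimated correlation, adjusted p = 0.415 without the 2 high 3' arrays). In each of these lists 2 genes fell with the 24 h arrays alone. The count was 3671, 544 and 429 without siCtrl vehicle replicate 1, siCtrl vehicle replicate 2 or siERK1 vehicle replicate 1, and the share higher moved from 51.6% to 63.9% with array medians subtracted.

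Without hormone at 24 h, the siCtrl and siERK2 groups each held a high 3' array, with GAPDH excesses of 5.54 and 5.73. CYP2C8 was 19.0-fold higher (log2 fold change 4.25, SE 0.26, adjusted p = 4.31e-09) and TSPAN8 14.1-fold higher. TFF1 was 11.9-fold higher (log2 fold change 3.57, SE 0.23, adjusted p = 1.07e-08). COL4A6, a basement membrane collagen gene, was 14.7-fold lower (log2 fold change -3.87, SE 0.26, adjusted p = 1.37e-08) and EGLN3 9.97-fold lower. These 5 also passed with the 24 h arrays fitted alone without the 2 high 3' arrays (adjusted p = 0.00141, 0.0207, 0.00015, 9.12e-05 and 0.00632), a fit of 1 array against 1 in which the other groups give the spread, but only 7 of the 20 genes taken by the naming rule did. In all, 829 genes passed, 471 higher and 358 lower, 687 of them by at least 1.5-fold, against 351.5 with no change simulated, 1130 without the 2 high 3' arrays and 344 with the 24 h arrays alone, and only 70 in all 3 fits. It was 46 with all 12 arrays of 24 h fitted alone and 7 with array weights. Of 33 DNA replication genes, 9 fell, 0 rose and 24 did not pass (15 fell adjusted over the list alone, median -0.49, adjusted p = 1.11e-09), with TYMS at -1.14, and with an estimated correlation this call was lost without the 2 high 3' arrays (adjusted p = 0.263). G2 and mitosis genes fell in 7 of 33 cases, 0 rose and 26 did not pass (16 fell adjusted over the list alone, median -0.56, adjusted p = 1.31e-08, adjusted p = 0.0878 with an estimated correlation). Of either list, 0 genes fell with the 24 h arrays alone. Of 18 ERK pathway output genes, 2 fell, 0 rose and 16 did not pass (4 fell adjusted over the list alone, median -0.18, adjusted p = 0.00825), DUSP6 at -1.85 (adjusted p = 0.195 with the 24 h arrays alone, where 1 gene of the list fell). The count was 2477, 2043 and 1852 without siCtrl vehicle replicate 1, siERK2 vehicle replicate 1 or siERK2 vehicle replicate 2, and the share higher moved from 56.8% to 69.0% with array medians subtracted.

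The siERK2 and siERK1 vehicle groups at 24 h, of which siERK2 holds a high 3' array at 5.73, differed most in CYP2C8, 22.2-fold higher in siERK2 cells (log2 fold change 4.47, SE 0.26, adjusted p = 1.33e-09). SLC1A1, a glutamate transporter gene, was 10.6-fold higher, also with the 24 h arrays alone (adjusted p = 0.0176). APOD, an apolipoprotein gene, was 9.70-fold lower (log2 fold change -3.28, SE 0.50, adjusted p = 0.000349), lost with the 24 h arrays alone (adjusted p = 0.0711). Of 33 G2 and mitosis genes, 18 were lower, 0 higher and 15 did not pass (21 lower adjusted over the list alone, median -0.83, adjusted p = 1.02e-14). PRC1, a regulator of cell division, changed by -1.26 (adjusted p = 0.0866 with the 24 h arrays alone). DNA replication genes were lower in 13 of 33 cases and higher in 1, with 19 not past (17 and 1 adjusted over the list alone, median -0.56, adjusted p = 4.35e-09). TYMS changed by -1.04. With the 24 h arrays fitted alone without the 2 high 3' arrays, 1 gene of the first list and 2 of the second were lower. In all, 1133 genes passed, 668 higher and 465 lower, 925 of them by at least 1.5-fold, against 373.5 with no change simulated, 1440 without the 2 high 3' arrays and 314 with the 24 h arrays alone. With all 12 arrays of 24 h fitted alone 36 passed, and with array weights 11. Only 110 genes passed in the 3 fits together, and 7 of the 20 taken by the naming rule passed with the 24 h arrays alone. The count was 3595 without siERK2 vehicle replicate 1 and 727 without siERK1 vehicle replicate 1.

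The difference of the E2 effect at 24 h between siERK1 and siCtrl cells passed for 224 genes, 128 higher and 96 lower, fewer than the 350 called with no change simulated. CXCL5, a chemokine gene, had a higher effect in siERK1 cells by 5.29 (SE 0.41, adjusted p = 1.28e-07, adjusted p = 0.0142 with the 24 h arrays alone without the 2 high 3' arrays). TMPRSS11E, a serine protease gene, differed by 4.29 and lost its call there (adjusted p = 0.0597). TFF1 differed by -3.42 (SE 0.33, adjusted p = 3.51e-06 and 0.00098), at 9.92 and 15.12 in siCtrl and 13.27 and 15.04 in siERK1 cells. Both E2 levels are near the array ceiling, so the difference follows the vehicle levels and saturation was not excluded. OLFML3, a secreted glycoprotein gene, differed by -3.06 (adjusted p = 0.274 with the 24 h arrays alone). Of 34 estrogen-induced genes, 3 had a lower effect, 0 a higher one and 31 did not pass (4 lower and 1 higher adjusted over the list alone, median -0.16, adjusted p = 0.0177, adjusted p = 0.136 with an estimated correlation), and 2 had a lower effect with the 24 h arrays alone. Of the 224 genes, 193 differed by at least 1.5-fold. Only 26 genes passed in the 3 fits together, 11 with all 12 arrays of 24 h fitted alone and 26 with array weights, and 5 of the 16 taken by the naming rule passed with the 24 h arrays alone. The count was 147 with the 24 h arrays alone, 550 without the 2 high 3' arrays and 135 without the dimmest genes. It was 2615, 409, 598 and 390 without siCtrl vehicle replicate 1, siCtrl E2 replicate 1, siERK1 vehicle replicate 2 or siERK1 E2 replicate 2.

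Between siERK2 and siCtrl cells the E2 effect at 24 h differed for 459 genes, 202 higher and 257 lower, against 373 with no change simulated. IGFBP3, an insulin-like growth factor binding protein gene, had a higher effect in siERK2 cells by 4.70 (SE 0.51, adjusted p = 1.2e-05, adjusted p = 0.0198 with the 24 h arrays alone). CGA differed by 4.45, lost there (adjusted p = 0.0754). TFF1 differed by -3.71 (SE 0.33, adjusted p = 7.65e-07 and 0.000329), at 13.49 and 14.97 in siERK2 cells, with the same limit at the ceiling. GREB1 differed by -3.60 (SE 0.40, adjusted p = 1.71e-05 and 0.00928), rising from 2.29 to 10.17 in siCtrl and from 4.61 to 8.89 in siERK2 cells. Both vehicle groups hold a high 3' array (GAPDH 5.54 in siCtrl and 5.73 in siERK2). Estrogen-induced genes had a lower effect in 11 of 34 cases and a higher one in 1, with 22 not past (15 and 4 adjusted over the list alone, median -0.41, adjusted p = 4.01e-05). PDZK1, a scaffold protein gene at the floor in both vehicle groups, differed by -3.10. DNA replication genes had a lower effect in 7 of 33 cases, 0 higher, and 26 did not pass (18 lower adjusted over the list alone, median -0.76, adjusted p = 9.01e-12), with GINS2 at -1.40 (adjusted p = 1.87e-05 and 0.0145), and with an estimated correlation this call was lost without the 2 high 3' arrays (adjusted p = 0.0756). G2 and mitosis genes had a lower effect in 5 of 33 cases, 0 higher, and 28 did not pass (8 lower adjusted over the list alone, median -0.73, adjusted p = 8.65e-07, adjusted p = 0.136 with an estimated correlation). Of 17 immediate early genes, 2 had a higher effect, 0 a lower one and 15 did not pass (5 higher and 1 lower adjusted over the list alone, median 0.51, adjusted p = 0.0013), KLF6 at 2.02 and ATF3 at 2.56, both transcription factor genes and both lost with the 24 h arrays alone (adjusted p = 0.335 and 0.342).

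Of the 459 genes of the difference between siERK2 and siCtrl cells at 24 h, 417 differed by at least 1.5-fold. With array medians subtracted the median of all genes was -0.13 and the share higher moved from 44.0% to 27.0%. The count was 317 with the 24 h arrays alone and 1107 without the 2 high 3' arrays, and 4 estrogen-induced genes and 1 gene each of DNA replication and of G2 and mitosis had a lower effect with the 24 h arrays alone, and 0 immediate early genes a higher one. Only 63 genes passed in the 3 fits together, 27 with all 12 arrays of 24 h fitted alone and 12 with array weights, and 9 of the 16 taken by the naming rule passed with the 24 h arrays alone. The count was 1855, 716, 1473, 1257 and 757 without siCtrl vehicle replicate 1, siCtrl vehicle replicate 2, siERK2 vehicle replicate 1, siERK2 vehicle replicate 2 or siERK2 E2 replicate 1.

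Between siERK2 and siERK1 cells the E2 effect at 24 h differed for 146 genes, 60 higher and 86 lower, fewer than the 361.5 called with no change simulated. CGA differed by 3.71 (SE 0.72, adjusted p = 0.00946) and IGFBP3 by 3.36 (SE 0.51, adjusted p = 0.000905), both lost with the 24 h arrays alone without the 2 high 3' arrays (adjusted p = 0.111 and 0.122). TMPRSS11E differed by -3.87 and TBC1D17, a gene of vesicle traffic, by -3.43, also lost (adjusted p = 0.0696 and 0.555). Of 17 immediate early genes, 1 had a higher effect, 0 a lower one and 16 did not pass (3 higher adjusted over the list alone, median 0.28, adjusted p = 0.00784). The cAMP and CREB target list passed upward (adjusted p = 0.0346, adjusted p = 0.147 with an estimated correlation) with 2 of 13 members higher and 0 lower (4 and 0 adjusted over the list alone), a mean of 0.56 and a median of -0.0022. Of these lists, 0 immediate early genes passed with the 24 h arrays alone, and 1 cAMP and CREB gene was higher and 1 lower. Of the 146 genes, 123 differed by at least 1.5-fold. With array medians subtracted the median of all genes was -0.14 and the share higher moved from 41.1% to 26.4%. The count was 39 without the dimmest genes, 542 without the 2 high 3' arrays and 194 with the 24 h arrays alone, and only 26 genes passed in all 3 fits. It was 17 with all 12 arrays of 24 h fitted alone and 19 with array weights. Of the 16 taken by the naming rule, 5 passed with the 24 h arrays alone. The count was 2168, 297, 252, 278 and 319 without siERK2 vehicle replicate 1, siERK2 vehicle replicate 2, siERK2 E2 replicate 1, siERK1 vehicle replicate 2 or siERK1 E2 replicate 2.

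The E2 response score at 24 h took 4198 genes and did not differ by the test. Its median was 0.79 in siCtrl, 0.62 in siERK1 (difference -0.16, fry adjusted p = 0.746) and 0.79 in siERK2 cells (difference 0.00035, adjusted p = 0.831). Without the 2 high 3' arrays the differences were 0.019 (adjusted p = 0.11) and 0.048 (adjusted p = 0.0552), so the siERK1 difference turned in sign, short of the test both times. The choice of genes also turned the direction at 24 h. With genes chosen in siCtrl cells alone the differences were -0.51 for siERK1 (adjusted p = 0.00312) and -0.39 for siERK2 (adjusted p = 0.00718). With the 100 genes of smallest p they were 0.43 (adjusted p = 2.64e-05) and 0.58 (adjusted p = 8.83e-07). The siERK1 score was -0.54 without siCtrl vehicle replicate 1, and the siERK2 score was -0.35 without that array and 0.28 without siERK2 vehicle replicate 1, all past the test.

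The E2 effect in siCtrl cells at 24 h differed from that at 4 h for 1261 genes, 556 higher and 705 lower, 1196 of them by at least 1.5-fold, against 42.5 with no change simulated. PTGS2, at the floor at 4 h with and without E2, had a higher effect at 24 h by 5.89 (SE 0.31, adjusted p = 2.51e-10). ID1, an inhibitor of differentiation, differed by 6.78 (SE 1.36, adjusted p = 0.00236), with an SD of 3.07 in the siCtrl vehicle group at 24 h, and by 4.61 without the 2 high 3' arrays (adjusted p = 1.81e-08). VTCN1 differed by -6.26 (SE 0.29, adjusted p = 4.95e-11) and TM4SF1 by -4.75. Of the 344 genes higher at 4 h, 149 were higher at 24 h (41.1 by chance), and of the 205 lower genes, 124 were lower (30.2 by chance). Beside the GAPDH 3' excess of 5.54 on 1 siCtrl vehicle array at 24 h, DNA replication genes had a higher effect at 24 h in 24 of 33 cases, 0 a lower one, and 9 did not pass (28 higher adjusted over the list alone, median 1.15, adjusted p = 1.04e-19). GINS2 differed by 1.48. G2 and mitosis genes had a higher effect in 17 of 33 cases, 0 a lower one, and 16 did not pass (26 higher adjusted over the list alone, median 1.14, adjusted p = 7.7e-15). CCNB2 differed by 1.27. Of 17 ribosome biogenesis genes, 4 had a higher effect, 0 a lower one and 13 did not pass (8 higher and 1 lower adjusted over the list alone, median 0.49, adjusted p = 0.00143). The count was 3538 without siCtrl vehicle replicate 1 of 24 h and 1647 without the 2 high 3' arrays, and the share higher moved from 44.1% to 56.1% with array medians subtracted.

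As lists, fibroblast and leukocyte markers passed in none of the 19 comparisons. The 8 measured fibroblast markers gave a smallest adjusted p of 0.278, and the 6 leukocyte markers 0.2.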

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

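The tests of the 3 patterns weighed here were all chosen after their results were seen, as were the splits taken after removing the mean siRNA effect; the plain splits were set before. Differences of the E2 effect are listed because the test of the difference itself passed. They come from the same model, and those at 24 h from fits that call 305 to 421 genes with no change simulated.

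At 4 h the E2 effect differed for 26 genes between siERK1 and siCtrl, 44 between siERK2 and siCtrl and 31 between siERK2 and siERK1. In the first comparison the differences were MTUS2 2.73, FILIP1L 2.22, OTUB2 1.83, CEACAM1 -2.25, HEG1 -2.21, ADM -2.16 and a median of -0.15 for estrogen-induced genes. In the second they were SSTR2 3.22, PLEKHO2 3.08, HSD11B2 2.35, KRT13 -2.55, GREB1 -2.54, TGFB2 -2.12, TFF1 -1.73, and medians of -0.082 for estrogen-induced and 0.26 for immediate early genes. In the third they were FST 3.09, LRRC15 2.77, SSTR2 2.49, BMP4 -2.04, BHLHE41 -1.62 and BDKRB2 -1.47. The E2 response score at 4 h was higher in siERK2 than in siCtrl cells by 0.18.

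At 24 h the E2 effect differed for 224, 459 and 146 genes in the same order. Between siERK1 and siCtrl the values were CXCL5 5.29, TMPRSS11E 4.29, TFF1 -3.42 and OLFML3 -3.06. For siERK2 against siCtrl they were IGFBP3 4.70, CGA 4.45, TFF1 -3.71, GREB1 -3.60, and medians of -0.41 for estrogen-induced, -0.76 for DNA replication and 0.51 for immediate early genes. For siERK2 against siERK1 they were CGA 3.71, IGFBP3 3.36, TMPRSS11E -3.87, TBC1D17 -3.43 and a median of 0.28 for immediate early genes. For TFF1, levels near the array ceiling with E2 at 24 h and in siERK2 cells at 4 h leave saturation open for each of its differences. Between 24 h and 4 h in siCtrl cells 1261 genes differed, with ID1 6.78, PTGS2 5.89, VTCN1 -6.26, TM4SF1 -4.75, and medians of 1.15 for DNA replication, 1.14 for G2 and mitosis and 0.49 for ribosome biogenesis genes.

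For the comparisons of 3 arrays with 3 at 4 h, the 10 splits of the 6 arrays are too few for a share under 0.05. The real splits gave 549, 552 and 833 genes for E2 in siCtrl, siERK1 and siERK2 cells, with highest other splits of 2, 4 and 3. In vehicle they gave 560, 839 and 1331 genes for siERK1 against siCtrl, siERK2 against siCtrl and siERK2 against siERK1, with highest others of 1, 1 and 3. In each of the 6, 1 split, the real one, gave as many genes.

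For the differences of E2 effects at 4 h, 100 splits exchanged the siRNA of arrays within vehicle and within E2. In 10, 7 and 12 of them, the real one included, as many genes passed as in the real split, for siERK1 minus siCtrl, siERK2 minus siCtrl and siERK2 minus siERK1. The highest others, 1536, 402 and 2535 genes against 26, 44 and 31, point to a structure of the samples: the exchanged arrays differ in siRNA, which alone changed 560 to 1331 genes. Such an exchange turns the siRNA effect into a difference of E2 effects, so these splits do not decide about chance. With the mean siRNA effect removed first, 1 of 100 splits, the real one, gave as many in each case. The highest other was 3 each time. This version was chosen after the plain splits were seen, and the arrays may be technical repeats, so chance is not excluded.

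The first pattern is the lower level of G2 and mitosis genes with siERK2 in vehicle at 4 h, with a median of -1.19 over 33 genes. Against siERK1 instead of siCtrl the median was -1.64 (upper quartile -1.46), which argues against siCtrl arrays that stand apart. With the GAPDH and ACTB 3' to 5' differences as covariates it was -1.16 (upper quartile -1.06) and with array medians subtracted -1.17 (upper quartile -1.04), which argues against RNA quality and scaling as the whole cause. Still open are an off-target effect of the siRNA, the extent of the ERK2 knockdown and a role of ERK2 itself, none of which these data test.

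The second pattern is the smaller E2 effect on estrogen-induced genes with siERK2 at 24 h, with a median of -0.41. Against siCtrl in vehicle, 9 of 34 members rose and 2 fell with siERK2 (median 0.16). Against siCtrl in E2, 0 rose and 7 fell (median -0.17). The smaller effect thus includes a higher vehicle level as well as a lower level with E2. Over the 32 members that stay more than 2 log2 units below the highest value of the arrays the median difference was -0.41. This argues against saturated signals as the cause. The camera test of this set alone gave an unadjusted p = 2.62e-05, and p = 0.00288 with an estimated correlation. Without the 2 high 3' arrays the median difference of the whole list was -0.62. The call, by an adjusted p, was kept with the preset correlation and lost with an estimated one. The part of these arrays therefore cannot be told apart, because the call depends on the correlation. Against siERK1 the median was -0.21 (camera adjusted p = 0.0608, adjusted p = 0.252 with an estimated correlation). A part of siCtrl arrays that stand apart therefore cannot be told apart either, with 2 arrays per group. A biological difference between the siRNAs stays open and was not tested further.

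The third pattern is the larger number of genes changed by E2 at 24 h in siCtrl (3195) than in siERK1 cells (2041). Without the 2 high 3' arrays the order turned, and siCtrl minus siERK1 gave -807 genes. Part of that turn is the siERK1 count, which went to 3397 through the spread shared by all groups. Without the siCtrl array alone the counts were 1791 and 2457, a difference of -666. Without the other siCtrl vehicle array, which also leaves 1, they were 4467 and 2459. The siCtrl count fell as far without siCtrl E2 replicate 2, whose GAPDH difference of 0.61 was not high. The fall is therefore not particular to the vehicle array with a high 3' signal, and the order of the counts depends on single arrays. No biological explanation was tested for it.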

How the results depend on the processing

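Settings chosen after the data were seen are named above with the alternatives. No paired analysis was possible because replicate numbers only count the arrays of a group and the labels mark no shared batch; a block by run of array numbers, possible at 24 h, is given below. Fewer arrays, and at 24 h 2 per group with a larger spread, limit the precision, and genes near the array floor have floor-limited changes. Unless said otherwise below, the cause of a change was not tested. Numbers are genes past the threshold, for siCtrl, siERK1 and siERK2 with E2, and for siERK1 against siCtrl, siERK2 against siCtrl and siERK2 against siERK1 in vehicle and for differences of E2 effects. The knockdown of MAPK3 at 4 h kept its direction and call under all settings, from -1.80 to -1.59.

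Using the values as deposited, all probe sets or no variance trend left each count within 1.5 times. With array medians subtracted, E2 in siERK2 cells at 24 h gave 5232. Without the dimmest genes, where fewer genes were tested, differences at 4 h gave 7, 13 and 13, and those at 24 h for siERK1 minus siCtrl and siERK2 minus siERK1 gave 135 and 39.

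With each time fitted alone, so that 24 h no longer shared the spread of 4 h, E2 at 4 h gave 945, 945 and 1437, vehicle at 4 h 1768, 1990 and 2844, and the siERK2 differences at 4 h 93 (minus siCtrl) and 68 (minus siERK1). E2 at 24 h gave 629, 487 and 586, vehicle at 24 h 16, 46 and 36, and differences at 24 h 11, 27 and 17.

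With array weights, E2 at 4 h gave 1652, 1688 and 1976, E2 at 24 h 265 in siCtrl and 224 in siERK2, vehicle at 4 h 2367, 2463 and 3117, vehicle at 24 h 14, 7 and 11, differences at 4 h 106, 221 and 174, differences at 24 h 26, 12 and 19, and 24 h minus 4 h 220. With the array number as a covariate, vehicle at 24 h gave 2578 and 1873 against siCtrl, differences from siCtrl at 24 h 519 and 1099, and 24 h minus 4 h 2161.

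The array numbers at 24 h form 2 runs, each with every group once; the labels do not call them batches. Deviations of arrays in the same run correlated by -0.21 to 0.65 between groups, with a median of 0.13, so the runs are not taken as pairs. With the run as a block, vehicle at 24 h gave 2275, 1781 and 1965, and the other counts stayed within 1.5 times. With the 24 h arrays alone and this block, E2 gave 595, 419 and 469, vehicle 6, 19 and 19, and differences 7, 19 and 7. The 2 high 3' arrays belong to the same run.

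With the siRNA effect averaged over vehicle and E2, siERK1 and siERK2 against siCtrl at 4 h gave 1536 and 1746, and siERK1 at 24 h 614. Reversed at 24 h were SAT1 for siERK1 (0.019, adjusted p = 1) and siERK2 (0.47, adjusted p = 0.00632) and GDF15 for siERK2 (0.23, adjusted p = 0.657).

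Without the 2 high 3' arrays, E2 at 4 h gave 835 in siCtrl and 1253 in siERK2, E2 in siERK1 at 24 h 3397, vehicle at 4 h 1207, 1559 and 2287, the siERK2 differences at 4 h 76 and 56, and differences at 24 h 550, 1107 and 542. With the 24 h arrays alone without them, E2 gave 953, 1089 and 989, vehicle 193, 344 and 314, and the difference siERK1 minus siCtrl 147. In both, the siCtrl and siERK2 vehicle groups at 24 h hold 1 array, assumed to vary like the other groups.

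With genes chosen in siCtrl, the E2 response score was -0.23 (adjusted p = 0.00204, reversed) for siERK1 and 0.0032 (adjusted p = 0.442) for siERK2 at 4 h, and -0.51 (adjusted p = 0.00312) and -0.39 (adjusted p = 0.00718, reversed) at 24 h. With the 100 genes of smallest p it was 0.43 (adjusted p = 2.64e-05, reversed) for siERK1 and 0.58 (adjusted p = 8.83e-07) for siERK2 at 24 h. With an estimated correlation 46 of the 97 list tests passed.

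With 1 array left out at a time, where a lone array was assumed to vary like the other groups, E2 at 24 h gave 1746 to 4467 in siCtrl, 1308 to 1803 in siERK1 and 1631 to 4258 in siERK2. Vehicle at 4 h gave 307 to 422 for siERK1 and 511 to 671 for siERK2, and at 24 h 429 to 3671, 969 to 2477 and 727 to 3595. Differences from siCtrl at 4 h gave 17 to 33 and 29 to 51, those at 24 h 190 to 2615, 309 to 1855 and 177 to 2168, and 24 h minus 4 h 930 to 3538. The score at 24 h was -0.54 to 0.0075 for siERK1, lowest without siCtrl vehicle replicate 1, and -0.35 to 0.28 for siERK2, reversed to -0.35 without siCtrl vehicle replicate 1 and highest without siERK2 vehicle replicate 1, all past the test there.

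Among changes of named genes, counted once per gene, comparison and setting, 575 kept direction and call with the values as deposited, 11 lost the call and 8 gained it. The counts were 582, 7 and 5 with array medians subtracted, 425, 123 and 17 with each time alone, 409, 156 and 29 with array weights, 545, 28 and 21 without the 2 high 3' arrays, and 184, 99 and 0 with the 24 h arrays alone.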

Other observations

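The comparisons of this part were chosen after the results were seen. In cells that received E2, the siRNA against ERK2 also went with lower cell cycle genes than siCtrl. At 4 h, 29 of 33 G2 and mitosis genes and 22 of 33 DNA replication genes fell, with medians of -1.37 and -0.81. At 24 h, 26 and 22 of them fell, with medians of -1.42 and -1.29, in a model that calls many genes at 24 h with no change simulated.

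FN1, the gene of the matrix protein fibronectin, rose with E2 at 24 h by 2.82 (SE 0.29, adjusted p = 6.68e-07) in siCtrl, 4.56 (SE 0.29, adjusted p = 9.49e-10) in siERK1 and 5.05 (SE 0.29, adjusted p = 1.76e-10) in siERK2 cells, each with 2 arrays per group. With the 24 h arrays alone, without the 2 high 3' arrays, it also passed (adjusted p = 0.0109, 0.00214 and 0.000788), though the siCtrl and siERK2 vehicle groups then hold 1 array each and borrow the spread of the others. The effect was higher in siERK2 than in siCtrl cells by 2.23 (adjusted p = 0.00309, and 0.031 with the 24 h arrays alone), while the list of basal and mesenchymal markers it belongs to did not pass for E2 in any of the siRNAs.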
